A study of Mus musculus with 12 samples.

How the data were processed

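Gene expression tables of 12 libraries were analysed as the authors deposited them, and no reads were processed here. The authors deposited RSEM expected counts per gene, estimated counts that need not be whole, in 1 table for the resting and 1 for the stimulated libraries, each with 55450 genes. Per the labels' protocols, polyadenylated RNA was made into libraries with a stranded ligation kit; whether counting used the strand is not given in the sources used here. Genes that overlap, antisense pairs and near-identical copies such as pseudogenes therefore carry some uncertainty in their counts. The submitters' processing notes name bcl2fastq 2.20, cutadapt 1.18, STAR 2.7.0f and RSEM 1.3.1 and the genome build mm10, without roles or settings. The deposited values were not normalized: their totals differ between libraries, and about 7% of the values in each library are not whole. Columns were matched to libraries by the letters that the labels give, and groups and replicate numbers were taken from the library titles. The labels give the culture time both as 24 hours and as overnight, and name the source both as spleen and lymph nodes and as splenocytes; they do not state the knockout's allele or driver. Gene symbols and coordinates (mm10, counted from 1) were taken by gene identifier from the GENCODE M21 annotation.

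Expected counts were rounded to whole numbers. Library totals ran from 63266477 to 76891786 counts, so that the floor of 3 counts per library used for genes at 0 lies at 0.0390 to 0.0474 CPM; floors cover counting error only, since reads are not independent molecules. Replicates of a group were compared by a chi-square over genes with at least 20 counts, and none was as close as sampling noise allows, so all 12 libraries were counted separately. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), scaled by TMM, and tested with edgeR 4.0.16 by its robust quasi-likelihood F-test in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. KO was compared with WT separately in the 6 resting and in the 6 stimulated libraries, without covariates. Stimulated cells were compared with resting cells in each genotype, and the difference between the genotypes' responses was tested, in 1 fit of the 4 group means over all 12 libraries. The raw counts of both tables entered that fit, and condition is also the table a library was deposited in. Log2 fold changes are given with their standard error, and CPM, a gene's count scaled to a fixed library total, as mean and SD over the 3 libraries of a group. Gene levels in CPM use the TMM-scaled library size of the fit, while marker sums and the CPM of Xist, Ddx3y, Gm47283 and Eno1 use the unscaled total.

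A set of 47 gene lists with 895 symbols, of which 2 were not in the tables, covered metabolism, cell state, cell death and markers of T cells and other blood cells. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01. Each was tested again with a correlation estimated per list, and with fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. With an estimated correlation camera called 0 lists in each of the 5 comparisons (1, 4, 13, 11 and 8 at an unadjusted p under 0.05 for resting, stimulated, stimulation in WT, stimulation in KO and the difference of responses), so every camera p is followed by the value with an estimated correlation where the list was called. Counts of list members are given over all genes tested and adjusted over the list alone.

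The groups, comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule took Pkm. It took up to 10 genes per direction with the largest change among genes past the threshold, with a mean of at least 3 CPM and, between 2 groups, without overlap of their libraries, leaving out predicted genes, pseudogenes and receptor or immunoglobulin segments. From each list described it took up to 4 members that passed with the largest change, or up to 2 with the highest mean if none passed. Not every gene it gives is named. Gm33707 and Gm10275 in resting cells, Mbnl1 and Gm33707 in stimulated cells, Gm38326, Gm47283 and the sequences compared with Gm33707 lie outside it and were chosen after their values were seen.

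The alternatives fixed beforehand were DESeq2's size factors in the same fit, the DESeq2 1.42.0 Wald test, no low-count filter, a filter of at least 1 CPM in 3 libraries (for the difference of responses also in 3 libraries of each condition), a non-robust fit, other sets of libraries in the fit, the replicate number as a block, and each library left out in turn. Those added after seeing the data were a covariate of the mean log2 CPM of markers of other cells, leaving out the resting libraries highest in erythroid transcripts or the marker genes themselves, leaving out chromosomes X and Y, and a correction for GC content and gene length by a robust loess trend per library (span 0.3). A least-squares trend was tried first for this correction and gave 3199 calls in stimulated cells, 630 of them higher, and a median log2 fold change of all genes of -0.06; it was replaced by the robust trend after this was seen.

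The tests were run on simulated counts made from the real libraries' means and totals, with 200 genes changed 1.5-, 2- or 4-fold in each of 5 draws. With dispersions on the trend over expression, the share of changed genes recovered at the smallest of these folds was 53.7% in resting cells (16394 to 16425 genes) and 90.1% in stimulated cells (14870 to 14893 genes). At 2-fold it was 73.4% and 98.5%. For stimulation it was 75.2% in WT and 79.1% in KO at the smallest fold, and for the difference of responses 52.2%. The share of false calls among all calls was 3.71%, 4.85%, 5.97%, 5.16% and 6.76% for resting, stimulated, stimulation in WT, stimulation in KO and the difference of responses. When each gene kept its own dispersion, these shares were 9.33%, 8.97%, 4.34%, 5.30% and 5.02%. The threshold of 0.05 bounds the expected share, which 5 draws estimate only roughly. With own dispersions, every draw lay above 5% in resting (8.11% to 10.6%) and in stimulated cells (7.43% to 11.8%). On the trend, so did every draw for the difference of responses (5.29% to 8.99%). In the other cases the draws lay on both sides of 5%. Recovery with own dispersions was 51.0% in resting and 87.8% in stimulated cells at the smallest fold, and 65.7% and 95.8% at 2-fold. A list shifted 1.3-fold was called by camera in every comparison simulated, with 0 to 2 of 43 to 45 other lists. Genes were simulated independently of each other, so this does not show how often camera calls unchanged lists of correlated genes. In the real stimulated libraries the estimated correlation of the B cell marker list was 0.94. Figures were drawn with matplotlib 3.10.9.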

Results

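Messenger RNA was sequenced from mouse CD4 T cells that lacked Pkm2 (KO) or were wild type (WT). Pkm encodes the pyruvate kinases M1 and M2, which make pyruvate in the last step of glycolysis, and Pkm2 is the M2 form that arises by alternative exon choice. Naive T cells from spleen and lymph nodes were cultured for 24 hours with interleukin 7 (IL7, 25 ng/mL), a cytokine that keeps naive T cells alive. The resting groups had IL7 alone. The stimulated groups also had plate-bound antibodies against CD3 (1 ug/mL) and CD28 (2 ug/mL), which trigger the T cell receptor and its main costimulatory receptor. Each of the 4 groups held 3 libraries. Total counts per library ranged from 63266477 to 72128433 in the resting and from 67333490 to 76891786 in the stimulated groups. The study's title names T cell survival and pyruvate oxidation as its subject, so genes of cell death and of pyruvate use are described in each condition. The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

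Pkm, the targeted gene, was lower in every KO library than in any WT library of the same condition. The gene lies on the plus strand of chromosome 9, from 59656368 to 59679375 in mm10. In resting cells it measured 511 ± 44.9 CPM (counts scaled to a fixed library total) in WT and 207 ± 12.3 in KO (SD, n = 3), with libraries at 481, 490 and 563 in WT and at 194, 217 and 211 in KO. In stimulated cells it measured 2209 ± 39.4 CPM in WT and 940 ± 15.1 in KO, with libraries at 2220, 2166 and 2242 in WT and at 944, 953 and 924 in KO. The log2 fold change of KO against WT was -1.30 ± 0.08 (SE) at rest and -1.23 ± 0.03 after stimulation (edgeR adjusted p = 0.0041 and 1.4e-08). Stimulation raised Pkm 5.47-fold in WT and 5.68-fold in KO, and the test of the difference between these responses gave a log2 value of 0.05 ± 0.10 (adjusted p = 0.83). The KO to WT ratio of CPM was 0.405 ± 0.0240 at rest and 0.426 ± 0.00682 after stimulation. These spreads are the KO SD divided by the WT mean and leave out the spread of WT. Taken relative to the summed counts of the glycolysis genes, a list without Pkm itself, the stimulated ratio was 0.463. Gene-level counts add the M1 and M2 transcripts, so the remaining counts were not assigned to either form. The resting call of Pkm was lost without KO resting replicate 2 or KO resting replicate 3, with adjusted p up to 0.0974.

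**Figure D1:**
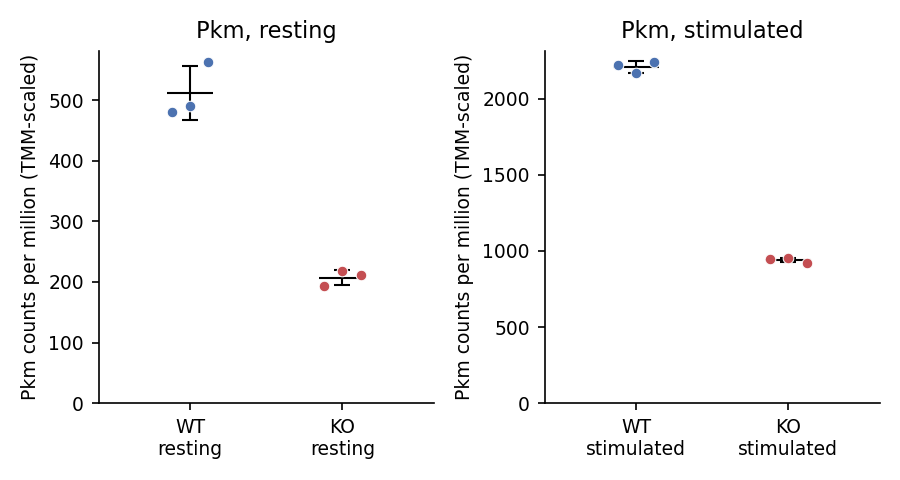
Pkm level in TMM-scaled CPM (linear axes from 0) in each of the 12 libraries, one point per library, with resting cells on the left and stimulated cells on the right; the wide line marks the group mean and the error bars 1 SD (n = 3). KO means were 207 and 940 CPM in resting and stimulated cells, against 511 and 2209 CPM in WT.

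The resting and stimulated libraries also differed in sex-linked transcripts. Xist, the RNA that coats the inactive X chromosome of female cells, lay between 822 and 1015 CPM in the 6 stimulated libraries and between 0.0577 and 0.0971 CPM in the 6 resting libraries. Ddx3y, a Y-linked RNA helicase gene, lay between 158 and 188 CPM in the resting libraries. The stimulated libraries held 0 counts of Ddx3y and of the other Y-linked genes of the list. Over all genes placed on chromosome Y they summed to 176 to 226 CPM, of which Gm47283 alone made up 175 to 225 CPM; it was at 100 to 145 CPM in the resting libraries. Both genotypes showed this pattern, so that genotype comparisons within a condition were made between libraries with the same sex-linked transcripts. In every comparison of stimulated with resting cells, condition and sex-linked transcripts change together and cannot be told apart.

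**Figure D2:**
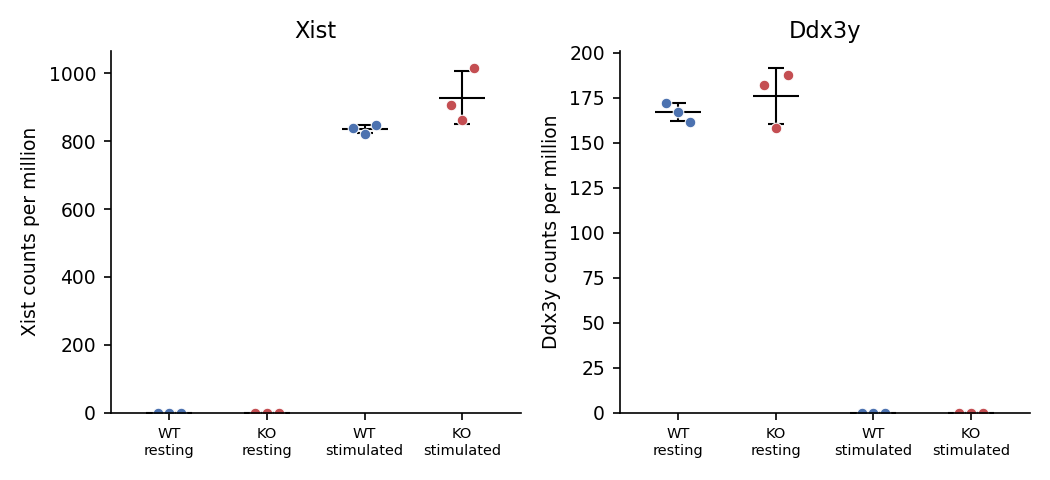
Xist (left) and Ddx3y (right) level in CPM (linear axes from 0) in each of the 12 libraries by group, one point per library, with lines at the group mean and error bars of 1 SD (n = 3). Xist was at 822 to 1015 CPM in the stimulated libraries, and Ddx3y at 158 to 188 CPM in the resting libraries.

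In resting cells, few genes separated the genotypes. Cxcr4, the chemokine receptor for Cxcl12, fell by 1.57 ± 0.06 on the log2 scale in KO, from 137 ± 8.24 to 46.0 ± 1.74 CPM (SD, n = 3, edgeR adjusted p = 0.00015). Mbnl1, a regulator of alternative splicing, rose 1.76-fold (log2 fold change 0.82 ± 0.07, adjusted p = 0.020), and Sox4, a transcription factor of lymphocyte development, rose from 18.3 ± 0.200 to 28.3 ± 1.27 CPM (log2 fold change 0.63 ± 0.05, adjusted p = 0.020). Gm33707, a processed pseudogene on chromosome 3 (60769887 to 60770455, mm10), had 0 counts in the 3 WT libraries and 27.0 ± 2.32 CPM in KO. That is at least 609-fold higher in KO, against a floor of 3 counts per library (adjusted p = 0.00015). The predicted gene Gm10275 fell by 0.38 ± 0.04 (adjusted p = 0.042). Gm33707 and Gm10275 were chosen after their values were seen.

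Gene groups of metabolism and survival held no called member in resting cells. None of 22 glycolysis genes, 15 pyruvate oxidation genes, 18 tricarboxylic acid (TCA) cycle genes, 10 apoptosis-promoting genes of the BCL2 family or 14 apoptosis-opposing genes passed over all genes tested. Adjusted over the list alone, 0 passed in the first 4 of these lists and 1, lower in KO, among the apoptosis-opposing genes. The glycolysis list had a median log2 fold change of -0.08 and the pyruvate oxidation list of 0.03, and neither passed camera (adjusted p = 0.061 and 0.26). Heat shock genes, which encode chaperones of protein folding, had a median of -0.65 in KO. None of 12 passed over all genes, and 11 were lower adjusted over the list alone. Hspa8 measured -0.47 ± 0.11 (adjusted p = 0.25) and Hsp90ab1 -0.47 ± 0.10 (adjusted p = 0.23). Camera with a preset correlation called the heat shock list lower (adjusted p = 3.2e-16), and the call was lost at adjusted p = 0.47 with an estimated correlation. Immediate early genes, which respond to handling as well as to signals, were lower beside them, with a median of -0.21, 0 of 18 passing over all genes and 5 lower adjusted over the list alone (camera adjusted p = 7.7e-05, and 0.60 with an estimated correlation). Interferon response genes had a median of -0.16, with 0 of 35 passing over all genes and 3 lower adjusted over the list alone (adjusted p = 9.8e-08 by camera, and 0.60 with an estimated correlation).

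Transcripts of other blood cells varied among the resting libraries. The summed level of 16 myeloid marker genes was 6016, 3102 and 1749 CPM in the WT libraries and 1571 ± 36.7 CPM in KO (SD, n = 3). The myeloid list had a median log2 fold change of -1.33 and 0 of 16 members passing, over all genes or adjusted over the list alone. Csf1r, the receptor of macrophage colony-stimulating factor, measured -1.46 ± 0.54 (adjusted p = 0.35). Camera called the list lower (adjusted p = 2.4e-10), and with an estimated correlation the call was lost at adjusted p = 0.60. Erythroid marker sums were 771 ± 863 CPM in WT and 696 ± 886 in KO, with replicate 1 of each genotype at 1731 and 1719 CPM. B cell marker sums were 4687 ± 1329 CPM in WT and 4742 ± 355 in KO. Markers of CD4 T cells summed to 7863 ± 596 CPM in WT and 8401 ± 268 in KO.

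In all, 6 of 16637 genes tested passed in resting cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3 higher and 3 lower in KO. At an unadjusted p under 0.05 there were 2284 genes, and DESeq2 called 518. The libraries of the groups did not overlap for 21.2% of the genes, where chance gives 10%. The number called was 18, 4 and 11 without WT resting replicates 1, 2 and 3, and 3, 2 and 2 without KO resting replicates 1, 2 and 3. Cxcr4 and Gm33707 passed in each of these 6 fits. Mbnl1, Sox4 and Gm10275 were each lost without WT resting replicate 2 and without each of the KO resting replicates 1, 2 and 3, with adjusted p up to 0.295 for Mbnl1 and Sox4 and 0.378 for Gm10275. Of 45 gene lists tested, camera called 18 with its preset correlation and 0 with an estimated one (smallest adjusted p = 0.47), and fry called 0 (smallest adjusted p = 0.18, with 7 at an unadjusted p under 0.05).

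In stimulated cells, KO libraries had higher levels of interferon response genes and of B cell and myeloid markers, and slightly lower levels of glycolytic and cholesterol synthesis genes. In these directions 17 of 35 interferon response genes, 1 of 17 B cell and 6 of 16 myeloid markers, 8 of 22 glycolysis genes and 10 of 23 cholesterol synthesis genes passed, and the camera call of each list was lost with an estimated correlation (adjusted p = 0.37). Apol7c, an apolipoprotein L family gene, rose by 1.34 ± 0.14 on the log2 scale, from 9.51 ± 0.147 to 24.2 ± 5.02 CPM (SD, n = 3, edgeR adjusted p = 0.0079). Tlr9, the receptor for unmethylated DNA, rose by 1.27 ± 0.14 (adjusted p = 0.0020). Icosl, the ligand of the costimulatory receptor Icos, rose from 2.04 ± 0.424 to 4.62 ± 0.671 CPM, and Fscn1, an actin-bundling protein of dendritic cells, rose by 1.10 ± 0.11 (adjusted p = 0.0070 and 0.0061). Dclk1, a microtubule-associated kinase, rose by 1.37 ± 0.23 (adjusted p = 0.021). Dapl1 fell by 0.80 ± 0.08 and Tfpi, an inhibitor of blood coagulation, fell by 0.69 ± 0.07 (adjusted p = 0.0013 and 0.0020). Trat1, an adaptor that stabilizes the T cell receptor complex, fell by 0.62 ± 0.09, and Tet1, an enzyme that oxidizes methylated cytosine, fell by 0.61 ± 0.12 (adjusted p = 0.018 and 0.024). Mbnl1 rose from 534 ± 9.17 to 915 ± 20.4 CPM (adjusted p = 9.0e-07). Gm33707 had 0 counts in the 3 WT libraries and 2.37 ± 0.296 CPM in KO, at least 58.2-fold higher (adjusted p = 5.1e-05); it and Mbnl1 were chosen after their values were seen.

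Of 35 interferon response genes tested, 17 rose, 1 fell and the rest did not pass; adjusted over the list alone, 25 were higher and 1 lower. Oasl1 and Oasl2, sensors and effectors of the antiviral response, rose by 1.59 ± 0.22 and 1.46 ± 0.29 on the log2 scale (edgeR adjusted p = 0.0070 and 0.044). Ifi213, an interferon-inducible gene, rose by 1.47 ± 0.20 and Rsad2, the antiviral enzyme viperin, by 1.34 ± 0.23 (adjusted p = 0.0070 and 0.013). Their levels were low, with Oasl1 at 1.10 ± 0.332 CPM in WT and 3.30 ± 0.624 in KO. The list's median was 0.79 (camera adjusted p = 1.2e-22), and the call was lost at adjusted p = 0.37 with an estimated correlation. Beside these genes, the summed level of 17 B cell marker genes was 963 ± 220 CPM in WT and 1615 ± 52.1 in KO, and that of 16 myeloid marker genes was 65.5 ± 12.7 and 112 ± 3.43 CPM.

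Markers of B cells and myeloid cells were higher in the KO stimulated libraries, and erythroid markers were not. NK cell, neutrophil and dendritic cell markers had medians of 0.44, 0.37 and 0.45, with 1 of 11, 0 of 8 and 1 of 6 passing over all genes as higher. Adjusted over the list alone, 1, 0 and 3 were higher and 0, 0 and 1 lower. Of the B cell markers, 1 of 17 passed over all genes and 16 were higher adjusted over the list alone, with Ighd, the heavy chain of immunoglobulin D, up by 0.94 ± 0.15 (edgeR adjusted p = 0.024). Of the myeloid markers, 6 of 16 rose, and 11 adjusted over the list alone, among them Csf1r (0.99 ± 0.22) and Spi1, a transcription factor of myeloid and B cells (0.75 ± 0.16). Their list medians were 0.83 and 0.77, and both camera calls (adjusted p = 3.2e-15 and 9.1e-10) were lost at adjusted p = 0.37 with an estimated correlation. Of 7 gamma-delta T cell markers 1 rose, also 1 adjusted over the list alone, namely Trdc, the constant region of the delta chain (1.00 ± 0.14), and camera's adjusted p of 0.0062 became 0.37 with an estimated correlation. Both tested CD8 T cell markers were higher adjusted over the list alone, with Cd8b1 up by 0.67 ± 0.08 (adjusted p = 0.0029). Of 22 memory or effector CD4 T cell genes, 7 rose, and adjusted over the list alone 11 were higher and 3 lower, with S100a4 (1.56 ± 0.22) and S100a6 (0.69 ± 0.13), calcium-binding proteins of motile cells, among them. That list's call (adjusted p = 1.9e-07 by camera) was also lost at adjusted p = 0.37 with an estimated correlation. Erythroid marker sums were 18.4, 69.9 and 19.7 CPM in the WT libraries and 24.5, 14.2 and 14.6 in KO. Of 6 erythroid markers tested, 1 had a log2 fold change above 0, the median was -0.99 and, by edgeR, 0 passed over all genes, adjusted over the list alone or at an unadjusted p under 0.05 (camera adjusted p = 0.33). CD4 T cell markers summed to 4241 ± 33.1 CPM in WT and 4261 ± 50.2 in KO, and 0 of 18 passed by edgeR, over all genes or adjusted over the list alone.

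**Figure D3:**
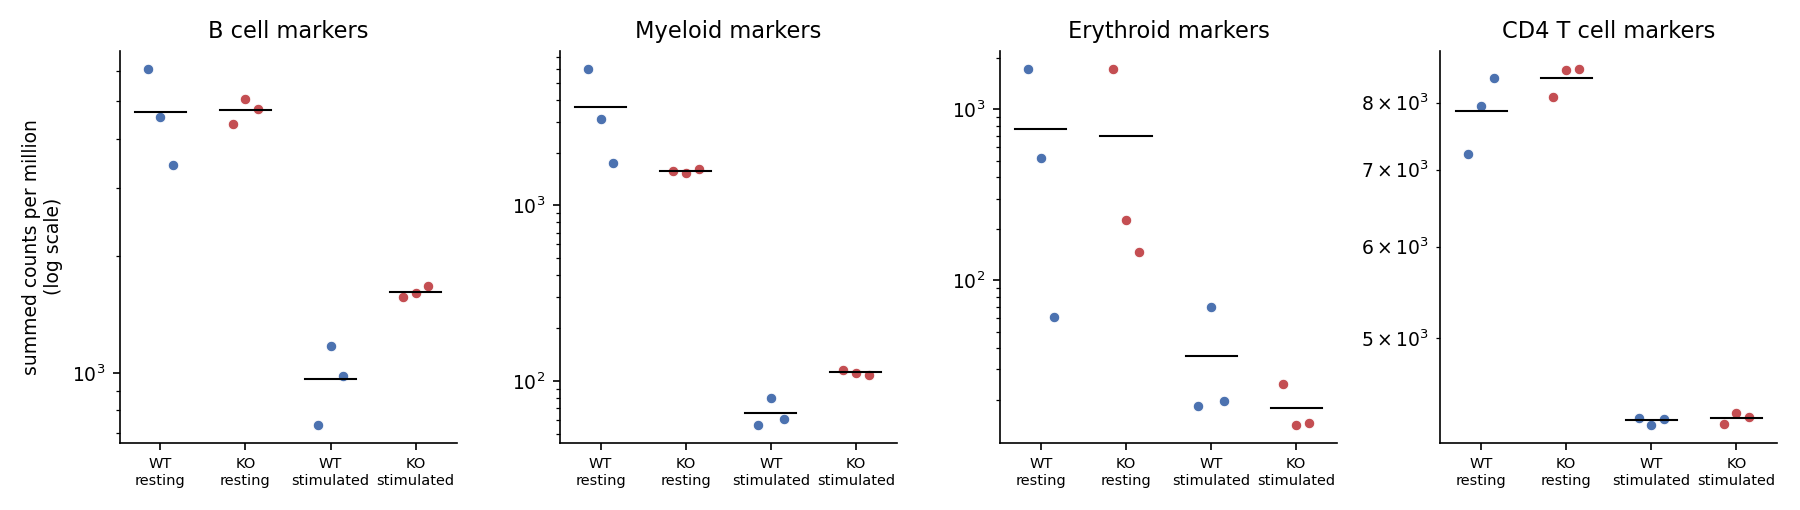
Summed CPM (log axes, 1 panel each) of marker genes of B cells, myeloid cells, erythroid cells and CD4 T cells in each of the 12 libraries by group, one point per library, with lines at the group mean. In stimulated cells B cell markers averaged 963 CPM in WT and 1615 CPM in KO, and CD4 T cell markers 4241 and 4261 CPM.

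Genes of glucose use were slightly lower in KO stimulated cells. Of 22 glycolysis genes, 8 fell and 0 rose, and 14 were lower adjusted over the list alone. Hk2, the hexokinase that traps glucose in the cell, fell by 0.23 ± 0.03 on the log2 scale, from 190 ± 3.46 to 162 ± 6.26 CPM (edgeR adjusted p = 0.0079). Slc2a1, the glucose transporter Glut1, fell by 0.16 ± 0.03 (adjusted p = 0.021), and the glycolytic enzyme genes Pgam1 and Tpi1 fell by 0.16 ± 0.03 and 0.16 ± 0.04 (adjusted p = 0.020 and 0.040). The median was -0.13 (camera adjusted p = 7.3e-10), and the call was lost at adjusted p = 0.37 with an estimated correlation. Of 15 pyruvate oxidation genes, 2 fell, and 3 were lower adjusted over the list alone, with a median of -0.04. Pcx, a member of this list that carboxylates pyruvate to oxaloacetate and does not oxidize it, fell by 0.31 ± 0.06 (adjusted p = 0.027). Pdha1, the E1 alpha subunit of pyruvate dehydrogenase, fell by 0.13 ± 0.03 (adjusted p = 0.037). With single libraries left out, the call of Pcx was lost in 5 of 6 fits and that of Pdha1 in 4 of 6. Camera called this list lower at adjusted p = 0.011, lost at adjusted p = 0.37 with an estimated correlation.

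The lists of TCA cycle, nuclear oxidative phosphorylation, cholesterol, fatty acid and serine and one-carbon genes had medians below 0 in KO stimulated cells. The 13 genes encoded in mitochondrial DNA had a median of 0.01, with 8 above 0 and, by edgeR, 0 passing over all genes, adjusted over the list alone or at an unadjusted p under 0.05 (camera adjusted p = 0.98). Of 18 TCA cycle genes, 2 fell, Idh2 and Suclg1, each by 0.15 ± 0.03, and 3 were lower adjusted over the list alone (camera adjusted p = 0.00055, and 0.37 with an estimated correlation). Of 49 nuclear genes of oxidative phosphorylation, 1 fell over all genes and 0 were lower adjusted over the list alone; the median was -0.07, and camera's adjusted p of 2.5e-07 became 0.42 with an estimated correlation. Cholesterol synthesis genes fell in 10 of 23 cases, and 18 were lower adjusted over the list alone. Mvd fell by 0.27 ± 0.06, Cyp51 by 0.25 ± 0.04, Lss by 0.24 ± 0.05 and Fdps by 0.24 ± 0.04, with edgeR adjusted p from 0.0091 to 0.037. The list's median was -0.16, and its call (adjusted p = 3.3e-14 by camera) was lost at adjusted p = 0.37 with an estimated correlation. Of 15 fatty acid synthesis genes, 2 fell, also 2 adjusted over the list alone, with Elovl6, a fatty acid elongase, at -0.38 ± 0.07 (list adjusted p = 0.00036, and 0.42 with an estimated correlation). Shmt1 and Psat1, enzymes of serine and one-carbon metabolism, fell by 0.14 ± 0.03 and 0.12 ± 0.03 in a list of 18 with 2 members lower, and 5 adjusted over the list alone (list adjusted p = 0.00029, and 0.37 with an estimated correlation).

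Of 28 genes of the G2 and M phases of the cell cycle, 5 fell in KO stimulated cells and 12 were lower adjusted over the list alone. Ube2c and Cdc20, which act with the anaphase-promoting complex, fell by 0.21 ± 0.05 and 0.18 ± 0.04, and Ccnb1, cyclin B1, fell by 0.17 ± 0.04 on the log2 scale (edgeR adjusted p = 0.037, 0.042 and 0.027). The median was -0.10 (camera adjusted p = 3.3e-08), and the call was lost at adjusted p = 0.40 with an estimated correlation. Of 22 genes of naive and quiescent T cells, 6 rose and 1 fell, and adjusted over the list alone 8 were higher and 1 lower. Cxcr4 rose by 0.75 ± 0.11 and Klf2, a transcription factor that keeps T cells quiescent, by 0.66 ± 0.09 (adjusted p = 0.0086 and 0.0061). S1pr1, the receptor for exit from lymph nodes, rose by 0.43 ± 0.09, and Ccr7, the receptor for entry, by 0.37 ± 0.04 (adjusted p = 0.028 and 0.0020). The list's median was 0.09, and its call (adjusted p = 0.00018 by camera) was lost at adjusted p = 0.37 with an estimated correlation. B cell markers, at 963 ± 220 CPM in WT and 1615 ± 52.1 in KO, were higher beside the naive genes as well.

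Some genes of cell death and of T cell activation passed in stimulated cells, where 719 of all 15090 genes tested passed. Of 10 apoptosis-promoting BCL2 family genes, Pmaip1, which encodes Noxa, rose by 0.51 ± 0.04 on the log2 scale (edgeR adjusted p = 0.00070), and 2 were higher adjusted over the list alone. Of 14 apoptosis-opposing genes, Birc2, an inhibitor of apoptosis protein, rose by 0.29 ± 0.05 (adjusted p = 0.011), and 2 were higher adjusted over the list alone. Camera called neither list (adjusted p = 0.13 and 0.25), while fry called the apoptosis-promoting list higher and not the opposing one (adjusted p = 0.011 and 0.24); the promoting list had a median of 0.01 with 6 of 10 genes above 0. Of 35 T cell activation genes, 1 rose and 3 fell, and adjusted over the list alone 2 were higher and 3 lower (camera adjusted p = 0.81). Tnfrsf9, the costimulatory receptor 4-1BB, rose by 0.43 ± 0.05, Cd40lg, the CD40 ligand, fell by 0.38 ± 0.06 and Tfrc, the transferrin receptor, fell by 0.18 ± 0.04 (adjusted p = 0.0024, 0.0098 and 0.032). Of 19 targets of NF-kB and tumour necrosis factor, 4 rose and 1 fell, and adjusted over the list alone 9 were higher and 1 lower. They included Cd83 (0.42 ± 0.08), Ltb (0.29 ± 0.03) and Lta (-0.23 ± 0.04), and the list's adjusted p was 6.8e-06 by camera and 0.40 with an estimated correlation. Of 18 immediate early genes, 5 rose, and adjusted over the list alone 8 were higher and 1 lower, with Dusp1 up by 0.43 ± 0.06 and Jun by 0.22 ± 0.05 (list adjusted p = 0.0019, and 0.38 with an estimated correlation). B cell and myeloid markers, with list medians of 0.83 and 0.77, were higher beside both of these lists.

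**Figure D4:**
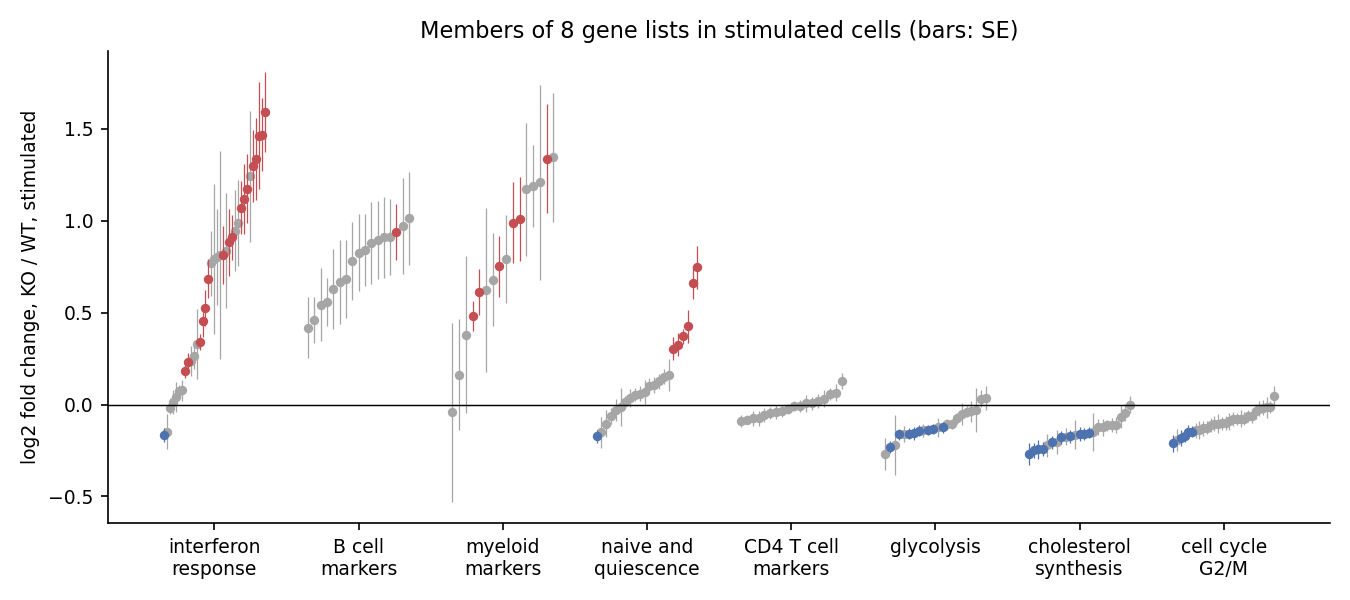
Log2 fold change of KO against WT in stimulated cells (linear axis, bars of 1 SE) for the tested members of 8 gene lists, one point per gene ordered by its value, in red where it passed as higher, in blue where it passed as lower and in grey where it did not pass over all genes. List medians were 0.79 for interferon response genes, -0.13 for glycolysis genes and -0.16 for cholesterol synthesis genes.

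In stimulated cells, 719 of 15090 genes passed by edgeR's quasi-likelihood test, 508 higher and 211 lower in KO, of which 141 and 10 differed at least 2-fold. The libraries of the groups did not overlap for 27.4% of the genes, where chance gives 10%. The number called was 458, 1408 and 262 without WT stimulated replicates 1, 2 and 3, and 221, 128 and 161 without KO stimulated replicates 1, 2 and 3; WT stimulated replicate 2 had an erythroid marker sum of 69.9 CPM, against 18.4 and 19.7 in the other WT libraries. Of 63 called genes named here or in the closing observations, 20 passed in each of the 6 fits, among them Pkm, Mbnl1, Gm33707, Cxcr4, Klf2, Ccr7, Pmaip1, Oasl1 and Dapl1. The calls lost were 17, 3 and 32 without WT stimulated replicates 1, 2 and 3, and 35, 42 and 35 without KO stimulated replicates 1, 2 and 3. With a covariate for markers of other cells, chosen after seeing the data, 1346 genes passed (723 higher and 623 lower), and 461 of the 719 were among them. Of the 63 named genes, 18 lost their call with this covariate, among them Apol7c, Dclk1, Trat1, Tet1, Tpi1, Pcx, S1pr1, Ighd, Csf1r and Spi1. DESeq2 called 1133 genes. A fit with all 12 libraries called 219, without 38 of the 63, while Pkm, Mbnl1, Oasl1, Cyp51, Klf2 and Ccr7 passed in it. Of 44 gene lists tested, camera called 26 with its preset correlation, 0 with an estimated one (smallest adjusted p = 0.37), and fry called 9, of which 7 were shared.

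Of the 6 genes called in resting cells, 4 were called in the same direction in stimulated cells. The few calls at rest limit how many could be shared. Among 14368 genes tested in both, Mbnl1 and Gm33707 were higher in KO in both conditions, where independent lists would share 0.105 genes, and Pkm and Gm10275 were lower in both, where they would share 0.0430. Cxcr4 was lower in KO at rest and higher after stimulation. These 4 shared genes became 40 at an unadjusted p under 0.01 (15 higher, with 12.7 from independent lists, and 25 lower, with 9.71), and 38 genes went in opposite directions. Of those 38, 34 were lower in KO at rest and higher after stimulation, and 4 the reverse. Across genes, which are not independent replicates, the log2 fold changes of both conditions had a Pearson r of -0.018 and a Spearman rho of -0.036.

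Most genes differed between stimulated and resting cells in both genotypes. Il2, the T cell growth factor, rose by 8.18 ± 0.31 on the log2 scale in WT and by 7.84 ± 0.31 in KO (edgeR adjusted p = 2.1e-09 and 3.3e-09, n = 3 per group). Crabp2, a carrier of retinoic acid, rose by 10.83 ± 0.14 and 10.64 ± 0.13, Fosl1, a transcription factor of the AP-1 family, by 9.84 ± 0.25 and 9.06 ± 0.23, and the cytokine gene Lif by 7.52 ± 0.17 and 7.04 ± 0.16. Ak4, a mitochondrial adenylate kinase, rose by 7.79 ± 0.19 and 7.73 ± 0.19, and Bcat1, the cytosolic branched-chain aminotransferase, by 7.05 ± 0.17 and 6.80 ± 0.17. S1pr1, Klf2 and Il7r, the IL7 receptor gene, fell, with log2 fold changes of -6.38 ± 0.09, -5.68 ± 0.08 and -4.19 ± 0.12 in WT and of -6.44 ± 0.09, -5.11 ± 0.08 and -4.14 ± 0.12 in KO. The naive and quiescence list, of 22 genes, had 17 lower and 4 higher in WT and 18 lower and 4 higher in KO, and the same counts adjusted over the list alone, with medians of -2.32 and -2.31 (adjusted p = 0.095 and 0.096 with an estimated correlation).

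Growth and metabolic genes rose after stimulation in WT and KO alike by direction. All 25 genes of Myc-driven ribosome biogenesis rose in both genotypes, by a median of 2.64 in WT and 2.39 in KO (adjusted p = 0.095 and 0.10 with an estimated correlation). Among them were Srm (4.23 ± 0.07 and 3.98 ± 0.07) and Odc1 (3.94 ± 0.12 and 3.82 ± 0.12), enzymes of polyamine synthesis, and the nucleolar protein gene Ncl (3.33 ± 0.08 and 3.21 ± 0.08). All 29 genes of the G1 and S phases and all 28 of G2 and M rose in both, with medians of 3.75 and 4.51 in WT and 3.65 and 4.02 in KO (adjusted p from 0.24 to 0.59 with an estimated correlation), with Uhrf1 at 5.40 ± 0.32 and 5.10 ± 0.32, Bub1 at 5.31 ± 0.41 and 4.90 ± 0.40 and Cdk1 at 5.19 ± 0.53 and 4.89 ± 0.52. Of 22 glycolysis genes, 18 rose and 3 fell in WT and 17 rose and 4 fell in KO, with medians of 1.99 and 1.91 (adjusted p = 0.10 in both with an estimated correlation). Hk2 rose by 4.33 ± 0.17 and 4.55 ± 0.18, Tpi1 by 4.06 ± 0.07 and 4.04 ± 0.07, and Pgam1 by 3.51 ± 0.05 and 3.47 ± 0.05. Of 23 cholesterol synthesis genes, 22 rose and 1 fell in both (medians 1.87 and 1.62, adjusted p = 0.11 and 0.13 with an estimated correlation), with Idi1 at 3.75 ± 0.05 and 3.47 ± 0.05 and Cyp51 at 3.18 ± 0.06 and 2.84 ± 0.06. All 18 TCA cycle genes rose in both (medians 1.12 and 1.05, adjusted p = 0.17 and 0.21 with an estimated correlation). Each of these list counts was the same adjusted over the list alone.

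Pyruvate oxidation and cell death genes moved in both directions on stimulation. Of 15 pyruvate oxidation genes, 10 rose and 5 fell in WT and 10 rose and 4 fell in KO, where 5 were lower adjusted over the list alone; camera called neither (adjusted p = 0.080 and 0.13). Of 10 apoptosis-promoting genes, 5 rose and 2 fell in WT and 6 rose and 2 fell in KO (camera adjusted p = 0.49 and 0.37), with Bax, a pore-forming death effector, up by 1.39 ± 0.04 and 1.40 ± 0.04 and Bmf, a BH3-only protein, at -4.63 ± 0.21 and -3.94 ± 0.20. Of 14 apoptosis-opposing genes, 8 rose and 5 fell in both (camera adjusted p = 0.14 and 0.072), with Bcl2l1, which encodes Bcl-xL, up by 3.34 ± 0.06 and 3.29 ± 0.06. Fry called the pyruvate oxidation list and both apoptosis lists higher in both genotypes. Apart from the 1 case given, the counts of these lists were the same adjusted over the list alone. All 16 myeloid markers fell in both genotypes, with medians of -7.19 and -4.82, and the same counts adjusted over the list alone (adjusted p = 0.50 and 0.59 with an estimated correlation). Of the 5 sex-linked genes tested, Xist rose by 13.97 ± 0.12 and 13.80 ± 0.12 and 4 Y-linked genes fell, with Ddx3y at least 3680-fold lower in WT and at least 3765-fold lower in KO. Both medians of that list, with such genes at their bound, were -10.93 and -11.04 (fitted -15.47 and -15.61, adjusted p = 0.095 and 0.096 with an estimated correlation, same counts adjusted over the list alone).

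In WT, 14682 of 17460 genes passed by edgeR on stimulation, 6861 higher and 7821 lower, and in KO 14467 passed, 6917 higher and 7550 lower. Of these, 6513 rose in both genotypes, 7135 fell in both, 9 went in opposite directions, 1025 passed in WT but not KO and 810 in KO but not WT, which is no test of a difference. Across genes, which are not independent replicates, the log2 fold changes of the genotypes had a Pearson r of 0.947. Markers of other cells fell as well, with B cell marker sums from 4687 CPM in resting to 963 in stimulated WT libraries. In KO libraries they went from 4742 to 1615 CPM. CD4 T cell marker sums fell too, from 7863 to 4241 CPM in WT and from 8401 to 4261 CPM in KO. Because condition, sex-linked transcripts and RNA of other cells change together, these counts of genes cover all of them. TMM scaling takes most genes as unchanged, while most were called here. Rises and falls on stimulation are therefore relative to the scaled library totals, and the amount of RNA per cell is not known. Camera called 26 of 46 lists in each genotype with its preset correlation and 0 with an estimated one (smallest adjusted p = 0.095 and 0.096).

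The difference between the genotypes' responses to stimulation was tested directly. Since sex-linked transcripts change with the condition, a genotype effect that depends on sex cannot be told apart from this difference. Cxcr4 had the smallest p, with a log2 difference of 2.30 ± 0.12 (edgeR adjusted p = 4.6e-06, n = 3 per group), since KO was lower at rest and higher after stimulation. Slc7a11, the cystine transporter, had a difference of 2.80 ± 0.41 (adjusted p = 0.015), the complement gene C4b of 2.92 ± 0.44 (0.016), Cd14, a myeloid receptor for lipopolysaccharide, of 2.77 ± 0.53 (0.049), and Cmklr1, the chemerin receptor, of 2.38 ± 0.46 (0.043). Apol7c had a difference of 1.80 ± 0.30 (adjusted p = 0.036) and S100a4 of 1.76 ± 0.25 (adjusted p = 0.016). Tnfsf4, the OX40 ligand, had a difference of -1.91 ± 0.31, Psrc1, a spindle protein gene, of -1.57 ± 0.23 and Phlda3, a p53 target, of -1.13 ± 0.16 (adjusted p = 0.018, 0.016 and 0.015). Tet1 had a difference of -0.80 ± 0.16 (adjusted p = 0.048).

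Of 35 interferon response genes, 7 had a higher difference and 0 a lower one, and 27 were higher adjusted over the list alone. Oasl1 (1.62 ± 0.26), Ifi213 (1.51 ± 0.21), Mx1 (1.49 ± 0.22) and Isg15 (1.38 ± 0.27) were among them, with edgeR adjusted p from 0.015 to 0.048. The median was 0.81 (camera adjusted p = 1.2e-36), and the call was lost at adjusted p = 0.074 with an estimated correlation. Beside these genes, the myeloid marker list had a median difference of 2.17, with 1 of 16 passing and 11 higher adjusted over the list alone (camera adjusted p = 4.3e-19, and 0.15 with an estimated correlation). Of 12 heat shock genes, Bag3, a co-chaperone, passed (0.65 ± 0.13, adjusted p = 0.043), and 9 were higher adjusted over the list alone, with a median of 0.65 (list adjusted p = 3.0e-14, and 0.074 with an estimated correlation). Of 22 naive and quiescence genes 4 passed, all with a higher difference, and 4 adjusted over the list alone. They were Cxcr4, Tsc22d3, a glucocorticoid-induced gene (0.92 ± 0.09), Txnip, an inhibitor of glucose uptake (0.58 ± 0.10), and Klf2 (0.57 ± 0.10; list adjusted p = 0.00031, and 0.35 with an estimated correlation). Ddit4, an inhibitor of mTOR signalling, had a difference of 0.82 ± 0.11, and the immediate early genes Dusp1 and Fos of 1.08 ± 0.16 and 1.09 ± 0.22 (adjusted p = 0.015, 0.015 and 0.047). Of 23 cholesterol synthesis genes, 2 passed with a lower difference, among them Lss (-0.47 ± 0.09), and 11 were lower adjusted over the list alone (list adjusted p = 1.2e-12, and 0.15 with an estimated correlation). By edgeR, 0 of 22 glycolysis genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.088).

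In this test 121 of 17460 genes passed by edgeR, 97 with a higher and 24 with a lower difference in KO, and 2772 had an unadjusted p under 0.05. With DESeq2's size factors in the same fit 125 passed, 87 higher and 38 lower, and the DESeq2 test itself called 1012. The number called was 238, 63 and 1646 without WT resting replicates 1, 2 and 3, 63, 52 and 56 without KO resting replicates 1, 2 and 3, 39, 217 and 42 without WT stimulated replicates 1, 2 and 3, and 55, 31 and 27 without KO stimulated replicates 1, 2 and 3. Of the 23 called genes named, Cxcr4, Phlda3, Slc7a11 and Tsc22d3 passed in each of these 12 fits. The calls lost were 1, 10 and 0 without WT resting replicates 1, 2 and 3, 8, 11 and 10 without KO resting replicates 1, 2 and 3, 14, 3 and 12 without WT stimulated replicates 1, 2 and 3, and 10, 15 and 17 without KO stimulated replicates 1, 2 and 3. WT resting replicate 3, without which the count was highest, had the lowest myeloid marker sum of the WT resting libraries, 1749 CPM. Camera called 27 of 46 lists, 0 with an estimated correlation (smallest adjusted p = 0.074), and fry called 9, all among the 27.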

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

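All tests of this part were chosen only after the results were seen, except the direct test of the difference of responses and the counts over other splits of the libraries; for the thinning to the lowest total, what would count for or against it was set before it was run.

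Cxcr4 had different genotype effects in the conditions by the direct test (log2 difference 2.30, edgeR adjusted p = 4.6e-06), lower in KO at rest and higher after stimulation. Apol7c differed by 1.80 (adjusted p = 0.036) and Tet1 by -0.80 (adjusted p = 0.048) in the same test. With single libraries left out, the calls of Apol7c and Tet1 were each lost in 9 of 12 fits (edgeR adjusted p up to 0.103 and 0.120). The call of Cxcr4 was lost in 0 of 12. Its mean level was 91.4 CPM over the resting libraries and 43.1 CPM over all 12 libraries. These 3 genes were singled out because the effect of the genotype differed between resting and stimulated cells. Sex-linked transcripts differ between these conditions as well, so a genotype effect that depends on sex cannot be told apart from 1 that depends on stimulation.

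The first pattern is that markers of B cells and myeloid cells, though not erythroid ones (list median -0.99), were higher in the KO stimulated libraries, together with the 719 genes called there. NK cell, neutrophil and dendritic cell markers in these libraries also had list medians above 0 (0.44, 0.37 and 0.45). The 211 genes called lower had a median log2 fold change of -0.19. For them, fewer T cells as the only difference is argued against, since CD4 T cell markers had a median of -0.0150 (quartiles -0.06 to 0.02). These markers themselves fell on stimulation in WT (14 of 18, median -0.75). A less advanced activation could therefore hide a loss of T cells, and the median cannot decide on both together. For the 719 genes as a set, a difference in depth or in GC content and length is argued against. Of these genes, 90.1% and 90.8% were called again after thinning to the lowest total and after the correction. For GC content and length this rests on the robust trend alone. The least-squares trend that it replaced gave 3199 calls, and how many of the 719 were among those was not counted. Fewer T cells stays open for the higher markers and the genes called higher, since a small loss would hardly move CD4 T cell markers, which summed to 4241 CPM in WT. It would raise the markers of other cells alike, and the log2 change of erythroid relative to B cell marker sums was -1.54, with a 95% Welch interval from -3.25 to 0.16 that holds 0. Without WT stimulated replicate 2, whose erythroid sum of 69.9 CPM was the highest of the stimulated libraries, that change was -1.07. RNA from other cells stays open too: with the marker covariate 64.1% were called again, the median size of change went from 0.41 to 0.36, its SE from 0.073 to 0.083, and all 719 genes kept their direction, but the covariate leans on WT stimulated replicate 2, whose marker score of 1.43 lies among the KO scores (1.27 to 1.45) where the other WT libraries have 0.26 and 0.60. A biological candidate explanation is a less advanced activation of KO cells: leaving out marker lists, 70.1% of the 489 genes called higher fell on stimulation in KO and 73.5% of the 211 called lower rose, against 37.1% and 46.1% of all genes, with shared KO libraries pushing these shares the other way. The first share lies just above the bound of 70% set for it. T cell activation genes, of which 33 of 35 rose on stimulation in each genotype, do not go along, with a median of 0.047 in KO against WT stimulated cells and 21 of 35 above 0. RNA from other cells may give the first share too, as other-cell genes also fell on stimulation, so these explanations cannot be told apart.

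The second pattern is the set of called genes beside Mbnl1 on chromosome 3, where Gm33707 is read in KO and not in WT. Reads shared with other annotated sequences are argued against. Of the 539 31-base words of Gm33707, Gm8483 holds 68, Gm4735 61, Eno1 60 and Eno1b 50. Eno1 was at 476 CPM or more in the WT libraries, which held 0 counts of Gm33707, and Gm4735 and Eno1b had at least 112 and 110 counts in each of them. Gm8483 and the 5 other sequences that share words had at most 3 counts in any library, against 1752 or more of Gm33707 in the KO resting libraries. An insertion or a strain variant near Mbnl1 stays open: leaving out Mbnl1, Gm33707 and Gm38326, 13.5% of genes within 5 Mb of Mbnl1 were called in stimulated cells against 4.72% elsewhere (5 of 37 genes, Fisher's exact p = 0.029, two-sided, in a window chosen for its calls). A difference of strain carried along with the altered allele stays open too. Within 5 Mb of Pkm, leaving out Pkm and Gm49759 inside it, 3.49% were called against 4.76% elsewhere (3 of 86 genes, odds ratio 0.72, 95% interval 0.15 to 2.2, Fisher's exact p = 0.80), too few to exclude an excess, and this window does not cover chromosome 3. No biological explanation was tested for this pattern.

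The third pattern is that Ddx3y, Eif2s3y, Kdm5d and Uty, which are Y-linked, were found in the resting libraries and Xist in the stimulated libraries, in both genotypes. Of the genes placed on chromosome Y, Gm47283 was read in all 12 libraries, at 175 to 225 CPM in the stimulated ones, where the others summed to at most 1.54 CPM. Without chromosomes X and Y, 14222 genes were called on stimulation in WT, 14032 in KO and 118 in the difference of responses. This leaves open how many of the calls on other chromosomes could come from the sex of the animals, since every resting library differs from every stimulated one in both ways and the condition cannot be told apart from sex.

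The number of genes called was set against other splits of the same libraries. For resting cells, stimulated cells and stimulation in WT and in KO, 1 of 10 splits, the real one, gave as many genes in each case, and 10 splits are too few for a share under 0.05. The real counts were 6, 719, 14682 and 14467, and the highest of the other splits 0, 1, 0 and 0. For the difference of responses, 3 of 100 splits drawn gave as many genes as the real 121. Splits that mix the genotypes carry genotype effects into the spread within groups, which lowers their counts. The share of 3 in 100 therefore cannot exclude chance. One of the others, with 295 genes, exchanged WT resting replicate 3 with KO resting replicate 1, and follows the order of other-cell markers at rest; another, with 202, reversed the labels in stimulated cells, which makes it a sum of the genotype effects.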

How the results depend on the processing

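The alternatives with the marker covariate, without the erythroid-high libraries, without marker genes, without chromosomes X and Y and with the correction for GC content and length were chosen only after the results were seen. Of 2402 values of named genes under alternatives, 2005 kept their direction and side of the threshold, 390 kept the direction and no longer passed, 6 newly passed and 1 changed sign: the difference of responses of Pkm, which was not called, ran from -0.0326 without WT resting replicate 3 to 0.106 without WT resting replicate 1. All 26 genes named for stimulation passed in each genotype under each alternative that tested them.

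Counts that moved by over 1.5 times were, for resting cells (6 genes), 518 with DESeq2, 40 without a filter, 161 with all 12 libraries in the fit, 157 with the marker covariate and 30 without the 2 erythroid-high libraries, and with single libraries left out from 2 to 18. For stimulated cells (719) they were 1133 with DESeq2, 219 with all 12 libraries, 1346 with the covariate and 128 to 1408 with single libraries left out. The least-squares trend first tried for GC content and length gave 3199. For the difference of responses (121) they were 1012 with DESeq2, 204 and 215 with the filters of 1 CPM in 3 libraries overall and in each condition, 209 without the erythroid-high libraries, the count with a replicate block given below and 27 to 1646 with single libraries left out. Stimulation counts stayed between 14358 and 14808 in WT and between 14040 and 14237 in KO with single libraries left out. The stimulated ratio of Pkm was 0.463 relative to glycolysis genes, which were themselves lower in KO. Genes shared by both genotype comparisons rose from 4 to 40 at an unadjusted p under 0.01. Lists called went to 0 with an estimated correlation in all 5 comparisons; with fry they were 0 in resting and 9 in stimulated cells, 43 for stimulation in each genotype and 9 for the difference of responses. With single libraries left out they were 14 to 22, 24 to 27, 26 to 30, 26 to 29 and 24 to 30. For the moved counts the cause was not tested.

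The replicate numbers did not pair the libraries throughout. At rest, correlations of deviations between same-numbered WT and KO libraries were 0.43, -0.21 and 0.43, and after stimulation -0.09, 0.04 and 0.08. Differently numbered WT and KO libraries at rest ran from -0.52 to 0.39. A factor shared within replicate 1 or within replicate 3 at rest therefore stays possible. With the number as a replicate block 5 genes passed in resting cells (4 shared), 997 in stimulated cells (694 shared), 14379 and 14214 for stimulation in WT and KO and 46 for the difference of responses (32 shared), with 19, 28, 28, 27 and 22 lists. In the last 3 fits the block joined same-numbered resting and stimulated libraries of a genotype. Their correlations were -0.24, -0.03 and 0.13 in WT and 0.13, 0.06 and 0.09 in KO. These libraries differ in sex-linked transcripts, so the block does not pair cells of 1 animal. The count of 46 is therefore no measure of an effect of pairing.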

Other observations

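The values of the last paragraph of this part, the counts of Gm38326, were looked up only after the results were seen; the lists of the other paragraphs were fixed before the data were examined.

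In stimulated cells, 4 of 23 helper lineage genes rose in KO and 7 were higher adjusted over the list alone. Rora, a transcription factor of interleukin 17-producing cells, rose by 0.68 ± 0.13 on the log2 scale (edgeR adjusted p = 0.019), Cxcr5, the chemokine receptor of follicular helper T cells and B cells, by 0.70 ± 0.14 (adjusted p = 0.047) and Cxcr3, a chemokine receptor of type 1 helper cells, by 0.31 ± 0.07 (adjusted p = 0.039). The list's call by camera (adjusted p = 0.0058) was lost at adjusted p = 0.40 with an estimated correlation, and B cell marker sums were 963 ± 220 CPM in WT and 1615 ± 52.1 in KO beside it. Of 24 targets of the hypoxia factor HIF1, 4 fell and 1 rose, and adjusted over the list alone 10 were lower and 1 higher. Higd1a, a mitochondrial hypoxia-induced protein gene, fell by 0.19 ± 0.04 and Egln3, an oxygen-sensing prolyl hydroxylase gene, fell by 0.19 ± 0.04, while Ndrg1, a stress-induced gene, rose by 0.32 ± 0.05 (adjusted p = 0.021, 0.020 and 0.013). The call (adjusted p = 0.00036 by camera) was lost at adjusted p = 0.37 with an estimated correlation. Of 20 caspase and death receptor genes, 2 rose, Mlkl, the executor of necroptosis (0.46 ± 0.11, adjusted p = 0.042), and Tnfrsf1b, a receptor of tumour necrosis factor (0.20 ± 0.05, adjusted p = 0.0495), and adjusted over the list alone 5 were higher and 1 lower (camera adjusted p = 0.38).

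In resting cells, antioxidant targets of Nrf2 had a median log2 fold change of -0.22 in KO, with 0 of 20 passing by edgeR over all genes and 4 lower adjusted over the list alone. Ftl1 and Fth1, the ferritin chains, measured -0.76 ± 0.22 and -0.41 ± 0.15 (adjusted p = 0.31 and 0.33). Camera called the list lower (adjusted p = 8.0e-08), and with an estimated correlation the call was lost at adjusted p = 0.60. Myeloid marker sums were 6016, 3102 and 1749 CPM in the WT libraries and 1571 ± 36.7 CPM in KO beside these genes. Nuclear genes of oxidative phosphorylation had a median of -0.07, with 0 of 49 passing over all genes or adjusted over the list alone (camera adjusted p = 7.1e-05, and 0.70 with an estimated correlation).

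Gm38326, a predicted gene, had 168 to 206 counts in the KO stimulated libraries and 1 to 11 in the WT stimulated libraries, and is given as values without an explanation.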
